A study of Mus musculus with 6 samples.

How the data were processed

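The libraries were 6 polyadenylated RNA libraries from engineered muscle constructs of the mouse C2C12 line, 3 treated with vehicle and 3 with TNF-alpha (100 ng/mL for 72 h), per the labels. They were prepared with a stranded mRNA kit and sequenced in paired-end mode, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, and each column of the table was matched to its sample by the library name in the labels. Contractile force, which the labels' protocols mention, was not analysed here.

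The deposited table holds estimated counts per gene, since between 20.1% and 21.0% of the values in a library carry decimals, as when a read is split between features, although the submitters' design text calls them integers. Per the submitters' processing notes, the builds were mm10 and GRCm38 and the tools named were TopHat2 2.1.1, Bowtie2 2.3.5.1, featureCounts from Subread 2.0.0 and DESeq2, with no role given for each. The options of the counting step, its use of strand and whether it counted reads or fragments are not given in the sources used here. Overlapping and antisense genes, and genes that share reads with a close paralog, are therefore uncertain. The table has 24421 rows, each naming a gene, of which 3813 were at 0 in every library. It has no symbols of mitochondrially encoded genes, so the planned share of counts in those genes was not computed. Per library, 81713008 to 93533748 counts were assigned to genes. Whether the reads come from independent molecules is not known. The edgeR p-values and intervals rest on the spread between libraries, whereas the chi-square values given below assume independent reads.

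The estimated counts were rounded to whole numbers before testing, in place of the raw whole counts that the plan had assumed. Genes with low counts were removed with filterByExpr of edgeR 4.0.16 (R 4.3.3), libraries were scaled with TMM, and TNF-alpha was tested against vehicle with the quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest), with group as the only term. Changes passed at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 12.1%. Standard errors of log2 fold changes were derived from the F statistic. CPM values were scaled with TMM and are given as mean ± SD (n = 3). Positions come from GENCODE M21 on GRCm38, in which 24001 symbols were found. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 23.1 to 70.6 for the 6 pairs, so none was counted as a duplicate.

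The 28 gene lists, holding 684 entries of which 646 were tested, were fixed before the data were examined, as were the tests and the rule for named genes. In 6 entries the table's older symbol was used (among them 8430408G22Rik for Depp1, Tmem8c for Mymk, Gm7325 for Mymx, Cyr61 for Ccn1 and Ctgf for Ccn2). Members were counted as risen or fallen by the edgeR test, with the adjustment over all genes and over the list alone. Each list was tested against other genes with camera of limma 3.58.1 on log2 CPM with a prior count of 2, using a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. The named genes were the 8 largest rises and 8 largest falls past the test with groups that did not overlap and a mean of at least 5 CPM in a group, passing over predicted genes, together with 12 fixed genes and 6 myosin heavy chain genes. They also held, for each list, the 2 members with the smallest p in the direction of most changes and 1 in the other. This gave 107 genes, of which some are not reported here. Another 12 genes with values, the gene Mybpc2 and other names listed without values were chosen after their values were seen.

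Shares of counts were compared with exact two-sided permutation tests of the difference of means, which cannot give a p under 0.1 for 3 against 3 libraries. For groups at 0, a floor of 3 counts per library was used. The procedure was tested on simulated counts drawn from each gene's mean over all 6 libraries, for 15795 genes of which 200 were changed. The edgeR test found 74% of the genes changed 1.5-fold, 74% of those changed 2-fold, 96% of those changed 4-fold and 98% of those changed 8-fold, and 11.4% of its calls were false, above the nominal level. In the same data 24.9% of the DESeq2 calls and 8% of the limma-voom calls were false. These shares come from a single draw with 200 changed genes, whereas 8769 genes were called in the real data. They therefore do not give the share of false calls there. Camera called 0 lists in simulated data with no change and the sarcomere list alone when it was lowered 2-fold. The simulated genes were drawn independently, whereas the estimated correlation reached 0.738 in a real list. The simulation therefore does not test camera's preset correlation on correlated lists.

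The alternatives were median-ratio and upper-quartile scaling, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, no robust estimation, the replicate number as a block, leaving out each library, thinning to the 81713008 counts of the shallowest library, a stricter adjusted p, and a test against a 1.5-fold change. Dropping the decimals and keeping only genes with whole counts were added after seeing the data. The estimates of GC content and transcript length used GENCODE M21, with values for 24045 symbols. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used for summaries, and matplotlib 3.10.9 for figures.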

Results

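Gene expression was measured by RNA sequencing in engineered skeletal muscle made from C2C12 cells, a mouse myoblast line that fuses into contractile myotubes when serum is lowered. The cells were cast in type I collagen between artificial tendons and differentiated. The constructs were then exposed for 72 h to tumour necrosis factor alpha (TNF-alpha, 100 ng/mL) or to its vehicle, phosphate-buffered saline. Each group held 3 constructs, numbered in the labels as biological replicates 1 to 3. No label says that the constructs came from separate cell batches, so the p-values measure the spread between these constructs. The deposited table held 24421 gene symbols, with 81713008 to 93533748 counts per library. Between 18317 and 18575 genes had a count above 0 in a library. The comparison asks which transcripts a prolonged exposure of muscle constructs to TNF-alpha raised or lowered.

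The TNF-alpha constructs carried far higher levels of many cytokine and chemokine transcripts and of the inducible nitric oxide synthase transcript, and lower levels of most transcripts of the contractile apparatus. Of 15795 genes tested, 4364 rose and 4405 fell by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, together 55.5% of the tested genes. Among these, 1337 rose and 1495 fell by at least 2-fold. In 10182 of the 15795 tested genes (64.5%) the 3 TNF-alpha libraries lay wholly on one side of the 3 vehicle libraries, where chance gives 10%. The first principal component of log2 CPM held 82.9% of the variance and separated the groups. The 85 ribosomal protein genes took 4.22% ± 0.20 of the counts in vehicle libraries and 3.41% ± 0.14 in TNF-alpha libraries (SD, n = 3). The 50 most abundant genes took 12.6% ± 0.26 and 13.0% ± 0.18.

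Of the 28 gene lists chosen in advance, 20 moved relative to other genes by limma's camera test with a preset correlation of 0.01, 8 upward and 12 downward. With the correlation estimated per list, camera called 0 lists after adjustment, with a lowest adjusted p of 0.415, and 2 at an unadjusted p under 0.05. Lists with unadjusted p from 0.0386 to 0.148 share the adjusted p of 0.415. The satellite-cell list had an estimated correlation of -0.033, below the preset, and its unadjusted camera p still went from 0.00502 to 0.0386. For that list a higher correlation does not account for the weaker result. With an estimated correlation camera takes its degrees of freedom from the 6 libraries and not from the genes. This gives a larger p at the same correlation, so the test has little power here. The directional test fry, which does not compare a list with other genes, called 24.

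**Figure D1:**
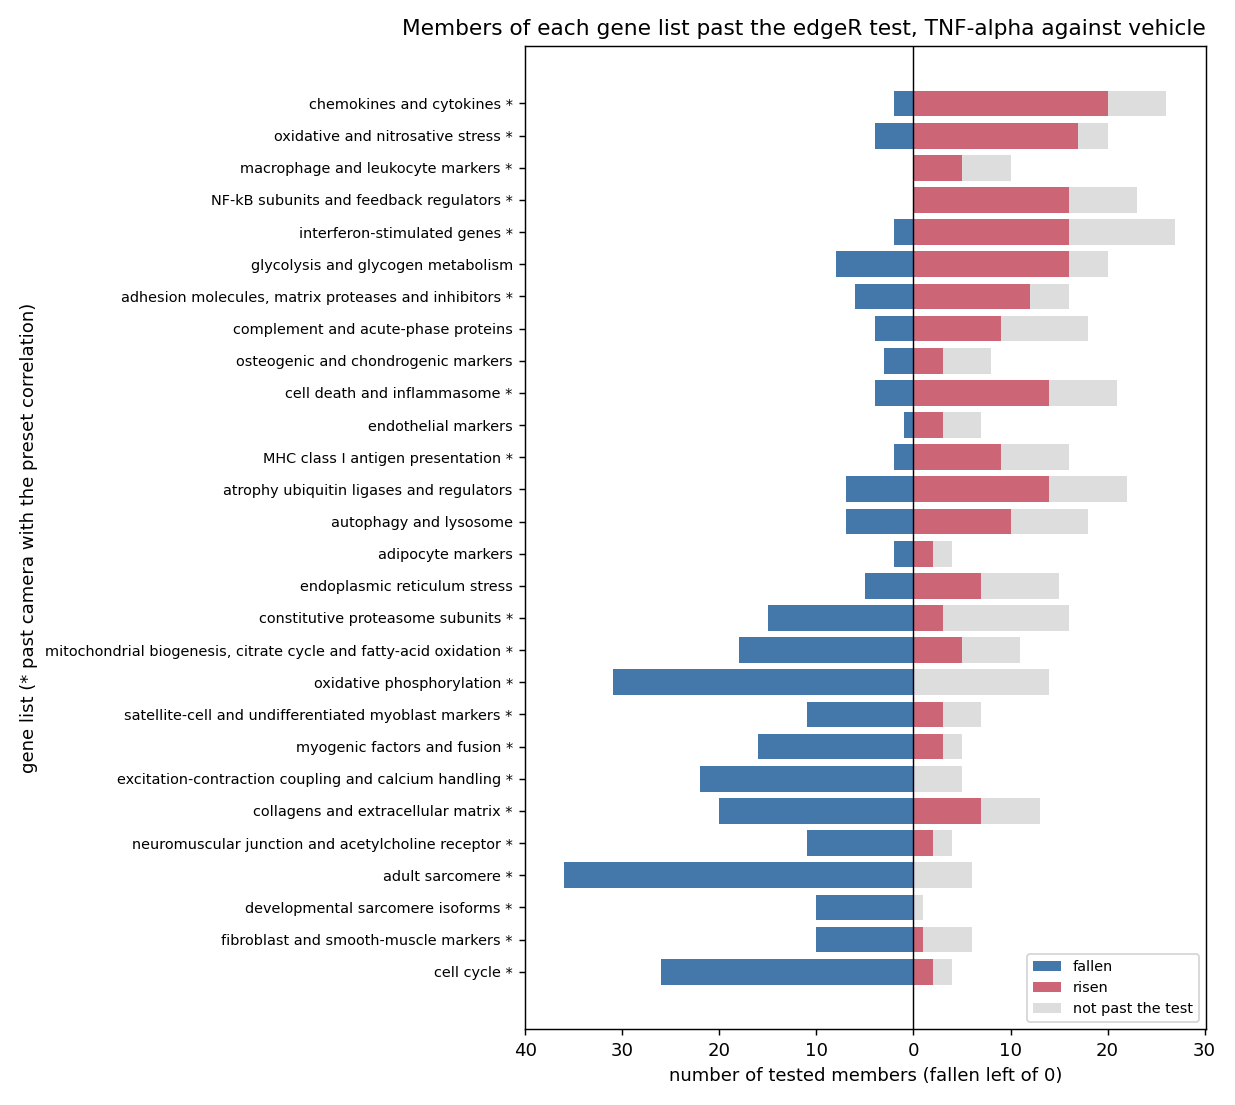
The bars give, for each of the 28 gene lists, the number of tested members that fell (left of 0), rose, or were not past the edgeR test (right of 0), ordered by the list's median log2 fold change, with an asterisk where camera with the preset correlation passed. The chemokine and cytokine list had 20 risen members of 28, and the adult sarcomere list had 36 fallen members of 42.

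Cytokine and chemokine transcripts were among the largest rises. Il6, which encodes interleukin 6 (GRCm38 chromosome 5, 30013114 to 30019981, plus strand), rose 128-fold, from 3.20 ± 1.30 to 409 ± 30.1 CPM (SD, n = 3; log2 fold change 7.00 ± 0.35 SE, adjusted p = 2.12e-05). Ccl5, a chemokine for T cells and monocytes, rose by 9.86 ± 0.37 on the log2 scale to 1055 ± 203 CPM (adjusted p = 3.84e-06). Il1a, encoding interleukin 1 alpha, rose by 8.45 ± 0.18 and Csf2, encoding the growth factor GM-CSF, by 8.40 ± 0.59. Of the 28 tested chemokine and cytokine genes, 20 rose, 2 fell and 6 were not past the test, with the same counts risen and fallen when adjusted over the list alone. Their median log2 fold change was 2.43 (camera adjusted p = 3.72e-05, and adjusted p = 0.415 with an estimated correlation). Csf3, encoding G-CSF, rose from 1 to 8 counts per vehicle library to 711 to 797 counts per TNF-alpha library (log2 fold change 7.41 ± 0.31, adjusted p = 5.43e-07). With so few vehicle counts, the Csf3 log2 fold change was 8.14 without vehicle replicate 2, in a range of 7.00 to 8.14. Cxcl1 and Ccl2, chosen after their values were seen, rose 7.72-fold and 5.55-fold. The members that fell were Il15, a cytokine made by muscle (log2 fold change -2.06 ± 0.13, adjusted p = 4.6e-06), and Cxcl12, which retains haematopoietic cells in marrow. The Tnf transcript itself had 27 to 48 counts in each of the 6 libraries (log2 fold change 0.00 ± 0.33, adjusted p = 0.999).

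Nos2, the inducible nitric oxide synthase gene (chromosome 11, 78920787 to 78960254, plus strand), rose 1303-fold. Its level went from 0.578 ± 0.544 CPM, with 11 to 109 counts per vehicle library, to 767 ± 105 CPM (log2 fold change 10.35 ± 0.59, adjusted p = 4.4e-05). Without vehicle replicate 3, the library with 109 counts, the Nos2 log2 fold change was 11.40, in a range of 9.90 to 11.40 over its alternatives. A cluster of small proline-rich protein genes on chromosome 3, known as components of the cornified envelope of skin, also rose. Sprr2d (92339140 to 92340873) had 0 counts in all 3 vehicle libraries and 16.2 ± 6.09 CPM in the TNF-alpha libraries, at least 484-fold higher when set against 3 counts per vehicle library. Sprr2e went from 0.0151 ± 0.0132 to 75.5 ± 21.5 CPM, Sprr2g from 0.0377 ± 0.0338 to 27.2 ± 7.65 CPM and Sprr2h from 0.0524 ± 0.0179 to 38.5 ± 6.62 CPM. These near-identical genes can share reads, and each had counts with decimals in 1 to 3 libraries, so the split between them is uncertain.

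**Figure D2:**
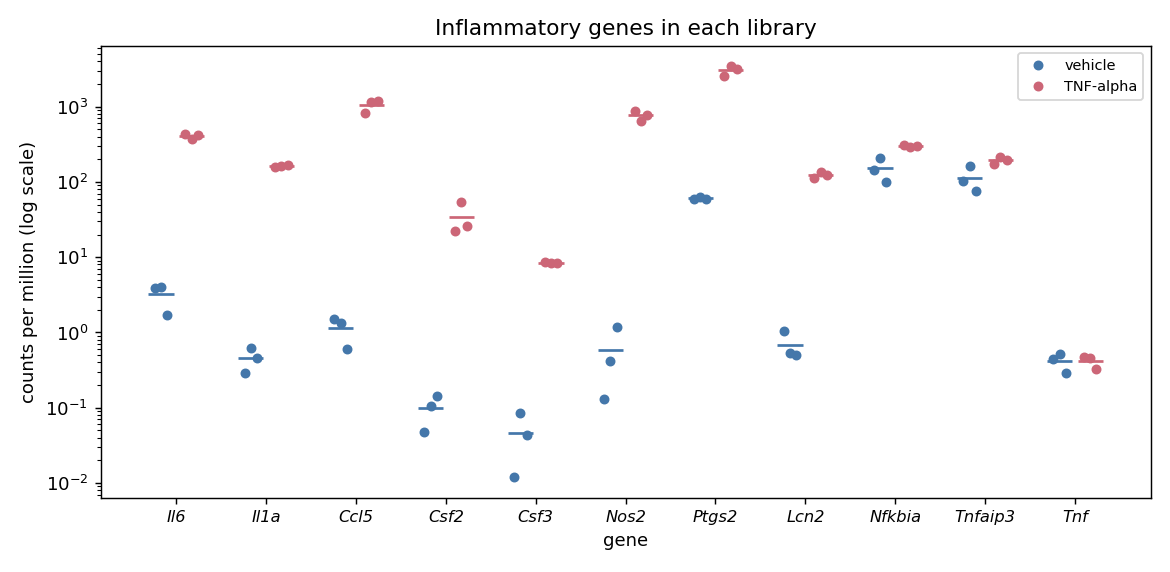
CPM (log axis) of 11 inflammatory genes, with a point for each of the 3 vehicle and 3 TNF-alpha libraries and a line at each group's mean. Il6 had means of 3.20 and 409 CPM, whereas Tnf had 0.417 and 0.416 CPM.

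Genes of the NF-kB pathway, the main transcriptional arm of TNF receptor signalling, rose with a lower median than the chemokine and cytokine genes. Of the 23 tested subunits and feedback regulators, 16 rose, 0 fell and 7 were not past the test, and 16 rose and 0 fell when adjusted over the list alone. The median log2 fold change was 0.89 (camera adjusted p = 6.1e-05, and adjusted p = 0.471 with an estimated correlation). Nfkb1, the p105 and p50 subunit gene, rose from 120 ± 9.74 to 284 ± 12.7 CPM (log2 fold change 1.25 ± 0.07, adjusted p = 3.35e-06). Traf1, a signalling adaptor of TNF receptors, rose 7.51-fold (2.91 ± 0.19 on the log2 scale, adjusted p = 1.11e-05). Nfkbia, encoding the NF-kB inhibitor IkB alpha, rose from 151 ± 55.6 to 299 ± 7.08 CPM (0.98 ± 0.26, adjusted p = 0.0197). Its adjusted p went to 0.0667 without vehicle replicate 1, 0.0569 without TNF-alpha replicate 1, 0.0551 without TNF-alpha replicate 3 and 0.0501 with no filter on low counts, within a range of 7.84e-04 to 0.0667 over its alternatives. Tnfaip3, encoding the NF-kB inhibitor A20, was not past the test (0.76 ± 0.29, adjusted p = 0.0689). Its adjusted p was 0.00104 without vehicle replicate 2, 0.0187 with limma-voom and 0.029 without robust estimation, within a range of 0.00104 to 0.17. Of the TNF receptor genes, Tnfrsf1a rose by 0.26 ± 0.06 (adjusted p = 0.00599) and Tnfrsf1b by 1.08 ± 0.12 (adjusted p = 1.65e-04).

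Interferon-stimulated genes rose in part. Of 29 tested, 16 rose, 2 fell and 11 were not past the test, with the same numbers risen and fallen when adjusted over the list alone (median log2 fold change 0.82). The GTPase gene Igtp rose by 1.06 ± 0.09 (adjusted p = 1.93e-05) and the RNA sensor gene Ddx58, encoding RIG-I, by 1.09 ± 0.10 (adjusted p = 3.43e-05). Ifit2, an inhibitor of viral translation, fell by 0.72 ± 0.15 on the log2 scale (adjusted p = 0.00552). Irf1, a transcription factor of the interferon response chosen after its values were seen, fell by 1.28 ± 0.36 (adjusted p = 0.0261). The Irf1 adjusted p was 0.0662 with no filter on low counts, and 0.0597, 0.0726, 0.0541 and 0.0748 without vehicle replicate 1 and without TNF-alpha replicates 1, 2 and 3, in a range of 2.11e-04 to 0.0748. The list passed camera (adjusted p = 0.0187, and adjusted p = 0.635 with an estimated correlation). Without TNF-alpha replicate 1 its adjusted p was 0.0648, in a range of 0.00586 to 0.635 over its alternatives.

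Class I antigen presentation genes rose modestly. Of 18 tested, 9 rose, 2 fell and 7 were not past the test, and 9 rose and 2 fell when adjusted over the list alone (median log2 fold change 0.26, camera adjusted p = 0.00958, and adjusted p = 0.507 with an estimated correlation). The class I heavy chain genes H2-K1 and H2-Q4 rose by 1.37 ± 0.06 and 0.94 ± 0.07 (adjusted p = 9.59e-07 and 1.28e-05), although these paralogs had decimal counts in all 6 libraries and can share reads. The members that fell were the endoplasmic reticulum chaperones Calr (-0.45 ± 0.08, adjusted p = 0.00156) and Pdia3. Among 22 complement and acute-phase genes, 9 rose, 4 fell and 9 were not past the test, and 9 rose and 4 fell when adjusted over the list alone. This list was not past camera (median 0.50, adjusted p = 0.138). Lcn2, an iron-scavenging acute-phase protein, rose 183-fold (7.51 ± 0.23, adjusted p = 8.36e-07) and Hp, encoding haptoglobin, rose by 6.16 ± 0.55 (adjusted p = 2.66e-04). The log2 fold change of Hp was 6.78 without vehicle replicate 1, in a range of 5.79 to 6.78. Saa3, an acute-phase serum amyloid gene chosen after its values were seen, rose 62.2-fold. Orm1, Orm2 and Lbp were among the members that fell.

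Of 24 tested genes of oxidative and nitrosative stress, 17 rose, 4 fell and 3 were not past the test, and 17 rose and 4 fell when adjusted over the list alone. Their median log2 fold change was 1.30 (camera adjusted p = 5.71e-04, and adjusted p = 0.415 with an estimated correlation). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose from 60.3 ± 2.32 to 3059 ± 431 CPM (5.66 ± 0.13, adjusted p = 3.84e-08), and the peroxiredoxin gene Prdx1 rose by 1.72 ± 0.10 (adjusted p = 2.5e-06). The NADPH oxidase gene Nox4 fell by 2.98 ± 0.13 (adjusted p = 6.36e-07), and Gpx3, Duoxa1 and Nos1 fell as well. Among 25 cell death and inflammasome genes, 14 rose, 4 fell and 7 were not past the test, and 14 rose and 4 fell when adjusted over the list alone (median 0.44, camera adjusted p = 0.0187, and adjusted p = 0.415 with an estimated correlation). The death receptor gene Tnfrsf10b rose by 1.85 ± 0.07 (adjusted p = 4.04e-07) and Mlkl, the effector of necroptosis, by 1.61 ± 0.09 (adjusted p = 1.97e-06). The members that rose also held Bax, Bak1, Bcl2l11, Ripk1, Ripk3, Zbp1, Gsdmd and Nlrp3, which promote cell death, and Bcl2l1, Mcl1, Cflar and Bcl2a1b, which inhibit it. Bcl2a1b had 0 counts in the vehicle libraries and at most 14.7 in a TNF-alpha library, at least 4.65-fold higher against 3 counts per library, and the list's median was 0.44 with this gene at its bound. Casp12, an inflammatory caspase, fell by 1.09 ± 0.07 (adjusted p = 3.86e-06), as did Casp1 and Bbc3.

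Endoplasmic reticulum stress genes moved both ways. Of 20 tested, 7 rose, 5 fell and 8 were not past the test, and 7 rose and 5 fell when adjusted over the list alone. Over all 15795 tested genes 4364 rose and 4405 fell, so the list's counts lie near the shares over all genes. The median log2 fold change was -0.05 while the mean was 0.29 and camera's direction was upward (adjusted p = 0.865). Ero1l, an oxidase of protein folding, rose 25-fold (4.64 ± 0.17, adjusted p = 5.37e-07) and the phosphatase regulator Ppp1r15a by 0.81 ± 0.06 (adjusted p = 1.6e-05). The chaperone gene Dnajc3 fell by 0.82 ± 0.08 (adjusted p = 3.46e-05).

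Most genes of the contractile apparatus fell. Of the 42 adult sarcomere genes tested, 36 fell, 0 rose and 6 were not past the test, and 37 fell and 1 rose when adjusted over the list alone. The gene that rose on that basis was Mybpc2, a fast myosin-binding protein C (log2 fold change 0.80 ± 0.29, adjusted p = 0.0595 over all genes), chosen after its values were seen. The list's median log2 fold change was -0.97 (camera adjusted p = 5.49e-10, and adjusted p = 0.415 with an estimated correlation). Tnnc2, encoding fast troponin C, fell from 652 ± 48.9 to 208 ± 13.8 CPM (-1.65 ± 0.08, adjusted p = 1.29e-06). Acta1, encoding skeletal alpha-actin and chosen after its values were seen, had 3437 ± 264 and 3344 ± 329 CPM (-0.04 ± 0.10, adjusted p = 0.759). Sarcomere genes took 2.69% ± 0.16 of the counts in vehicle libraries and 1.55% ± 0.08 in TNF-alpha libraries (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The list of developmental sarcomere isoforms held 11 genes, among them Ncam1 and Nes, which are not sarcomere isoforms. Of the 11 genes, 10 fell, 0 rose and 1 was not past the test, and 10 fell and 0 rose when adjusted over the list alone (median -1.29, camera adjusted p = 8.2e-05, and adjusted p = 0.415 with an estimated correlation). Ncam1, also in the neuromuscular junction list, was among those that fell, and Nes was the gene not past the test. Myl6b, a myosin light chain gene, fell 4.94-fold (adjusted p = 4.18e-07). The share of counts in ribosomal protein genes was also lower in these libraries, at 3.41% against 4.22%.

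All 6 myosin heavy chain genes examined fell, but by different amounts. Myh2, the fast 2A isoform (chromosome 11, 67171027 to 67197517, plus strand), fell 11.4-fold, from 250 ± 28.9 to 21.8 ± 3.42 CPM (-3.52 ± 0.14, adjusted p = 1.13e-06). Myh1, the fast 2X isoform, fell by 3.03 ± 0.19, neonatal Myh8 by 2.66 ± 0.17, embryonic Myh3 by 2.45 ± 0.16 and the fast 2B isoform Myh4 by 1.83 ± 0.28 on the log2 scale. The slow isoform Myh7 (chromosome 14) fell by 1.23 ± 0.33 (adjusted p = 0.0222). Its adjusted p was 0.0642 without TNF-alpha replicate 1, 0.0518 without TNF-alpha replicate 2 and 0.0571 with no filter on low counts, in a range of 0.00431 to 0.0642. Together the 6 genes took 0.551% ± 0.065 of the counts in vehicle libraries and 0.0928% ± 0.0143 in TNF-alpha libraries (exact two-sided permutation p = 0.1). As a share of their sum, Myh1 went from 32.5% ± 2.16 to 23.1% ± 3.03, Myh2 from 4.58% ± 0.068 to 2.33% ± 0.19, Myh4 from 4.0% ± 0.19 to 6.46% ± 1.68 and Myh7 from 4.78% ± 1.51 to 12.2% ± 2.87. The Myh4 difference of 2.46 percentage points was 1.51 without TNF-alpha replicate 2, in a range of 1.51 to 3.08 without 1 library. Each of these 4 shares had the smallest possible exact permutation p of 0.1 (0.15 adjusted over the 6 genes). The shares of Myh3 (44.5% ± 4.33 and 46.9% ± 2.16) and Myh8 (9.61% ± 0.60 and 9.0% ± 2.15) had exact permutation p = 0.6 and 0.7. These shares are not corrected for transcript length, and the genes, 5 of them neighbours on chromosome 11, had decimal counts in all 6 libraries and can share reads.

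**Figure D3:**
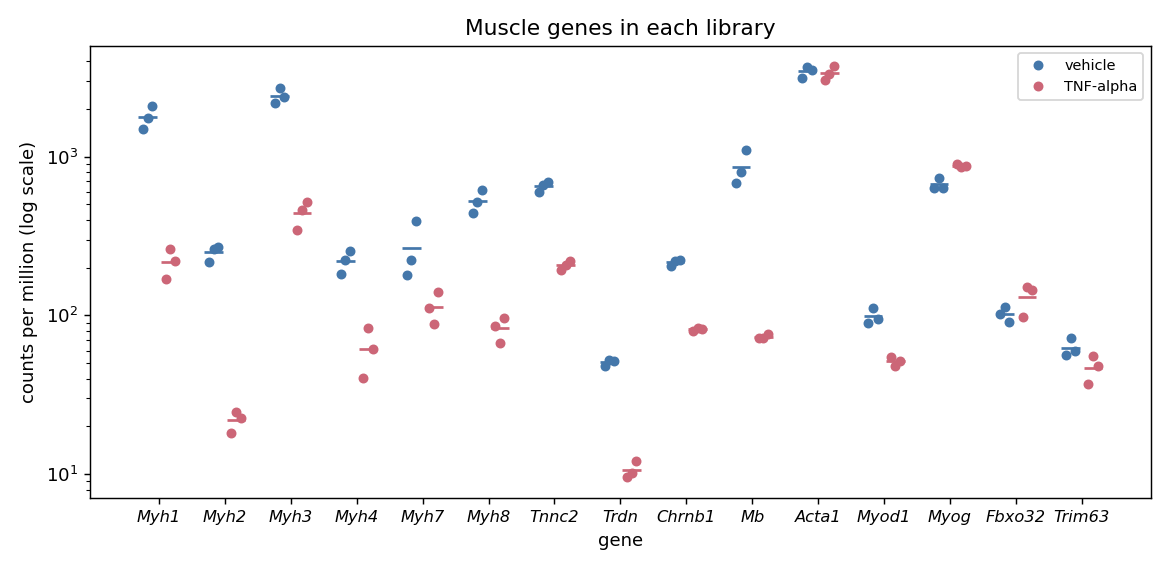
CPM (log axis) of 15 muscle genes, with a point for each of the 3 vehicle and 3 TNF-alpha libraries and a line at each group's mean. Myh2 had means of 250 and 21.8 CPM, whereas Acta1 had 3437 and 3344 CPM.

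**Figure D4:**
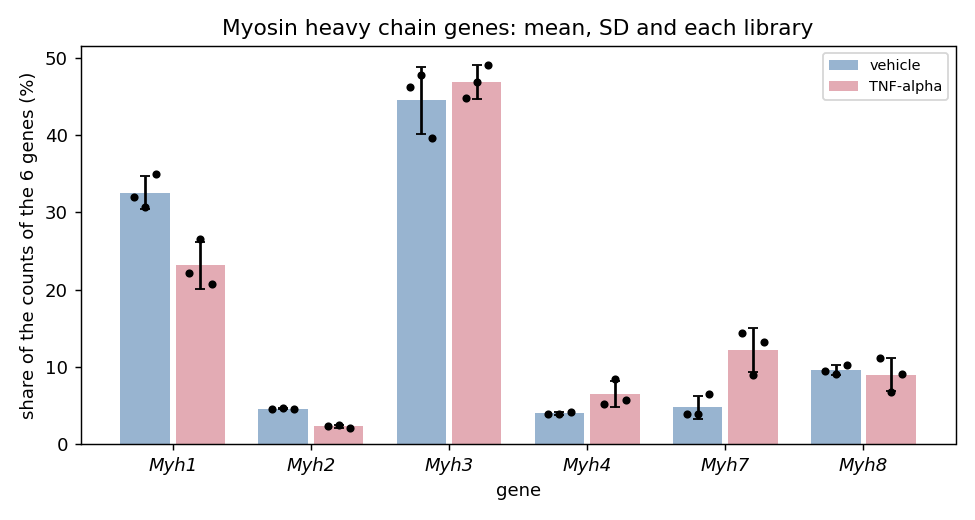
Share of each myosin heavy chain gene in the counts of the 6 genes (%), with bars at the mean of 3 libraries, error bars of 1 SD and a point per library. Myh7 had means of 4.78% and 12.2%, and Myh1 of 32.5% and 23.1%.

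Regulators of the muscle programme also fell for the most part. Of 21 myogenic and fusion genes, 16 fell, 3 rose and 2 were not past the test, and 16 fell and 3 rose when adjusted over the list alone (median -0.66, camera adjusted p = 5.71e-04, and adjusted p = 0.415 with an estimated correlation). Smarcd3, a chromatin remodelling subunit of muscle and heart, fell by 1.32 ± 0.07 (adjusted p = 2.01e-06), and the determination factor gene Myod1 by 0.95 ± 0.09 (adjusted p = 3.96e-05). The differentiation factor gene Myog rose, from 669 ± 57.4 to 878 ± 24.98 CPM (0.39 ± 0.08, adjusted p = 0.00281), and so did Mef2d and Myf5. Markers of satellite cells and undifferentiated myoblasts fell as well. Of 18 tested, 11 fell, 3 rose and 4 were not past the test, and 11 fell and 3 rose when adjusted over the list alone (median -0.62, camera adjusted p = 0.00958, and adjusted p = 0.415 with an estimated correlation). The Notch target genes Heyl and Hey1 fell by 4.99 ± 0.33 and 2.51 ± 0.21 (adjusted p = 1.13e-05 and 2.19e-05). Sdc4, encoding syndecan 4, rose by 0.88 ± 0.08 (adjusted p = 3.26e-05), as did Id2 and Cd34.

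Transcripts of membrane excitation and calcium release were lower too. Of 27 excitation-contraction coupling genes, 22 fell, 0 rose and 5 were not past the test, and 22 fell and 0 rose when adjusted over the list alone (median -0.72, camera adjusted p = 1.36e-05, and adjusted p = 0.421 with an estimated correlation). Trdn, encoding the calcium-release complex protein triadin, fell from 50.8 ± 2.50 to 10.6 ± 1.28 CPM (-2.26 ± 0.10, adjusted p = 5.71e-07). Stac3, required for the coupling of the calcium channel to the ryanodine receptor, fell by 1.72 ± 0.08 (adjusted p = 1.14e-06). Of 15 neuromuscular junction genes, 11 fell, 2 rose and 2 were not past the test, and 11 fell and 2 rose when adjusted over the list alone (median -0.82, camera adjusted p = 0.00472, and adjusted p = 0.489 with an estimated correlation). The acetylcholine receptor subunit gene Chrnb1 fell by 1.40 ± 0.06 (adjusted p = 5.99e-07) and the agrin receptor gene Lrp4 by 1.26 ± 0.08 (adjusted p = 3.84e-06). Agrn, encoding agrin, rose by 1.06 ± 0.10 (adjusted p = 4.56e-05), and the transcription factor gene Etv5 rose.

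The best known ubiquitin ligase genes of muscle atrophy were not past the test. Fbxo32, encoding atrogin-1, had 102 ± 11.0 CPM in vehicle and 131 ± 28.6 CPM in TNF-alpha libraries (log2 fold change 0.36 ± 0.17, adjusted p = 0.104). Trim63, encoding MuRF1, had 62.4 ± 8.23 and 46.8 ± 9.19 CPM (-0.42 ± 0.16, adjusted p = 0.0576). Of 29 atrophy genes tested, 14 rose, 7 fell and 8 were not past the test, and 15 rose and 8 fell when adjusted over the list alone (median 0.21, camera adjusted p = 0.138). The muscle ubiquitin ligase gene Fbxo40 rose 3.83-fold (1.94 ± 0.13, adjusted p = 1.23e-05) and Eif4ebp1, an inhibitor of translation, rose by 0.92 ± 0.07 (adjusted p = 1.1e-05). The stress-response gene Sesn1 fell by 1.06 ± 0.06 (adjusted p = 3.44e-06). Mstn, encoding myostatin, was filtered out, with 0 to 14 counts per library. Without TNF-alpha replicate 1, Fbxo32 had an adjusted p of 0.00181, and 0.0372 with DESeq2, in a range of 0.00181 to 0.279. Trim63 had an adjusted p of 0.0208 without TNF-alpha replicate 2 and of 0.0138 with DESeq2, 0.0362 with limma-voom, 0.0417 with upper-quartile scaling and 0.0424 without robust estimation, in a range of 0.00292 to 0.152.

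Autophagy genes moved both ways and proteasome subunit genes fell slightly. Of 25 autophagy and lysosome genes, 10 rose, 7 fell and 8 were not past the test, and 11 rose and 8 fell when adjusted over the list alone (median 0.16, camera adjusted p = 0.488). By comparison, 4364 of all 15795 tested genes rose and 4405 fell. The mitophagy receptor gene Bnip3l rose by 1.42 ± 0.10 (adjusted p = 1.06e-05) and the lysosomal protease gene Ctsl by 1.04 ± 0.08 (adjusted p = 1.26e-05), while the autophagosome protein gene Map1lc3a fell by 1.05 ± 0.07 (adjusted p = 5.15e-06). Of 31 constitutive proteasome subunits, 15 fell, 3 rose and 13 were not past the test, and 15 fell and 3 rose when adjusted over the list alone. Their median log2 fold change was -0.16 (camera adjusted p = 0.00996, and adjusted p = 0.635 with an estimated correlation). The ATPase subunit genes Psmc3 and Psmc5 fell by 0.81 ± 0.07 and 0.57 ± 0.06 (adjusted p = 1.61e-05 and 6.41e-05), and Psmd11 rose by 0.72 ± 0.06 (adjusted p = 2.8e-05), with Psma6 and Psmd8.

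Nuclear-encoded genes of oxidative phosphorylation fell by small amounts. Of 45 tested, 31 fell, 0 rose and 14 were not past the test, and 31 fell and 0 rose when adjusted over the list alone (median -0.26, camera adjusted p = 1.97e-06, and adjusted p = 0.443 with an estimated correlation). The complex I gene Ndufs8 fell by 0.97 ± 0.08 (adjusted p = 1.97e-05) and the ATP synthase gene Atp5o by 0.63 ± 0.05 (adjusted p = 2.44e-05). Of 29 genes of mitochondrial biogenesis, citrate cycle and fatty-acid oxidation, 18 fell, 5 rose and 6 were not past the test, and 20 fell and 5 rose when adjusted over the list alone (median -0.26, camera adjusted p = 0.00686, and adjusted p = 0.415 with an estimated correlation). Mb, encoding the oxygen-binding protein myoglobin, fell from 859 ± 213 to 73.5 ± 2.55 CPM (-3.55 ± 0.18, adjusted p = 4.62e-06). The isocitrate dehydrogenase gene Idh2 fell by 1.01 ± 0.06 (adjusted p = 4.4e-06) and Ppargc1a, a coactivator of mitochondrial biogenesis, by 1.08 ± 0.17 (adjusted p = 6.73e-04). Ppard, a nuclear receptor of lipid metabolism, rose by 1.99 ± 0.08 (adjusted p = 5.98e-07), as did Esrra, Nrf1, Cpt2 and Cpt1b.

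Glycolysis and glycogen genes moved both ways. Of 28 tested, 16 rose, 8 fell and 4 were not past the test, and 16 rose and 8 fell when adjusted over the list alone. The median log2 fold change was 0.71 and the list was not past camera (adjusted p = 0.169). Slc2a1, encoding the glucose transporter GLUT1, rose from 121 ± 15.9 to 1172 ± 42.5 CPM (3.28 ± 0.11, adjusted p = 1.59e-07). Pfkfb3, which makes an activator of phosphofructokinase, rose by 2.21 ± 0.09 (adjusted p = 5.19e-07), and the lactate dehydrogenase gene Ldha, chosen after its values were seen, rose 2.22-fold. Ckm, encoding muscle creatine kinase, fell by 1.71 ± 0.07 (adjusted p = 4.8e-07). The muscle enolase gene Eno3 and muscle phosphoglycerate mutase gene Pgam2, both chosen after their values were seen, fell by 1.83 ± 0.10 and 1.32 ± 0.10. The other genes that fell were Pfkm, Pygm, Phka1, Slc2a4 and Ldhb. Without vehicle replicate 3 the list passed camera, with an adjusted p of 0.0186 (range over its alternatives 0.0186 to 0.748).

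The largest falls included genes for secreted and matrix proteins, a methyltransferase and transporters. Inmt, a methyltransferase of indole amines, went from 143 ± 32.7 CPM to 0.0413 ± 0.0155 CPM, with 2 to 5 counts per TNF-alpha library. Igf1, a growth factor for muscle (chromosome 10, 87858265 to 87937042, plus strand), fell 174-fold, from 73.3 ± 11.3 to 0.417 ± 0.147 CPM (-7.44 ± 0.23, adjusted p = 5.43e-07). Cilp, a cartilage matrix protein, fell by 5.68 ± 0.37, the matrix protein gene Dpt fell by 5.56 ± 0.13 and the collagen gene Col28a1 fell by 5.48 ± 0.31. The transporter genes Slc6a7 and Slc6a2, for proline and noradrenaline, had log2 fold changes of -5.62 ± 0.29 and -5.51 ± 0.12, both past the test, and Tmc3 fell by 5.58 ± 0.26. Of 33 collagen and extracellular matrix genes, 20 fell, 7 rose and 6 were not past the test, and 20 fell and 7 rose when adjusted over the list alone (median -0.76, camera adjusted p = 0.00472, and adjusted p = 0.489 with an estimated correlation). Col15a1, a basement membrane collagen, fell by 4.99 ± 0.21 (adjusted p = 6.8e-07) and Col6a2 fell by 1.88 ± 0.12 (adjusted p = 9.56e-06). Lox, which cross-links collagen, rose by 1.83 ± 0.08 (adjusted p = 7.85e-07).

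Adhesion and protease genes rose more often than they fell. Of 22 adhesion molecules, matrix proteases and inhibitors, 12 rose, 6 fell and 4 were not past the test, and 12 rose and 6 fell when adjusted over the list alone (median 0.54, camera adjusted p = 0.0407, and adjusted p = 0.549 with an estimated correlation). The metalloproteinase inhibitor gene Timp1 rose by 1.16 ± 0.07 (adjusted p = 4.61e-06). Mmp9, encoding gelatinase B and chosen after its values were seen, rose 118-fold. Adamts5, an aggrecan-cleaving protease, fell by 1.92 ± 0.16 (adjusted p = 5.35e-05). Without TNF-alpha replicate 2 the list's adjusted p was 0.0557, in a range of 0.002 to 0.549 over its alternatives.

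Cell cycle transcripts fell. Of 30 tested, 26 fell, 2 rose and 2 were not past the test, and 26 fell and 2 rose when adjusted over the list alone (median -1.94, camera adjusted p = 1.97e-06, and adjusted p = 0.489 with an estimated correlation). The replication helicase gene Mcm6 fell by 1.90 ± 0.10 (adjusted p = 1.71e-06) and the kinase gene Cdk2 by 0.90 ± 0.06 (adjusted p = 4.32e-06). Ccnd1, encoding the G1 cyclin D1, rose by 1.66 ± 0.19 (adjusted p = 3.49e-04), and the S-phase transcription factor gene E2f1 rose.

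Markers of other cell types moved in different directions. Fibroblast and smooth-muscle markers fell, with 10 of 16 fallen, 1 risen and 5 not past the test, and 10 fallen and 2 risen when adjusted over the list alone (median -1.31, camera adjusted p = 0.00124, and adjusted p = 0.415 with an estimated correlation). Pi16, a marker of adventitial fibroblasts, fell by 5.36 ± 0.19 (adjusted p = 3e-07), whereas the growth factor receptor gene Pdgfra rose by 0.60 ± 0.18 (adjusted p = 0.0251). The Pdgfra adjusted p was 0.0737, 0.0576 and 0.0711 without vehicle replicates 1, 2 and 3, 0.0723 without TNF-alpha replicate 3 and 0.0522 with no filter on low counts, in a range of 2.83e-04 to 0.0737. Of 10 tested macrophage and leukocyte markers, 5 rose, 0 fell and 5 were not past the test, and 5 rose and 0 fell when adjusted over the list alone (median 0.93, camera adjusted p = 0.0249, and adjusted p = 0.415 with an estimated correlation). With no filter on low counts the adjusted p of the macrophage and leukocyte markers was 0.0637, in a range of 2.28e-04 to 0.415, and with the stricter filter their median was 2.05, in a range of 0.76 to 2.05. The stricter filter put the median of the fibroblast and smooth-muscle markers at -2.26, in a range of -2.26 to -1.04. The lysosomal membrane gene Cd68 rose from 4.81 ± 0.04 to 19.8 ± 0.74 CPM (2.04 ± 0.08, adjusted p = 5.1e-07), and Csf1r, the receptor of macrophage growth factors, rose by 2.54 ± 0.25 (adjusted p = 5.32e-05).

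Endothelial, adipocyte and bone or cartilage markers were not past camera. Of 8 endothelial markers, 3 rose, 1 fell and 4 were not past the test, and 3 rose and 1 fell when adjusted over the list alone (median 0.43, in a range of 0.08 to 0.81 over the alternatives, camera adjusted p = 0.371). The secreted protein gene Egfl7 rose by 1.45 ± 0.18 and the receptor gene Flt1 by 0.93 ± 0.15 (adjusted p = 1.82e-04 and 6.93e-04), and the angiopoietin receptor gene Tek fell by 2.00 ± 0.26 (adjusted p = 2.57e-04). Of 6 adipocyte markers, 2 rose, 2 fell and 2 were not past the test, and 2 rose and 2 fell when adjusted over the list alone. Their median and mean were 0.03 while camera's direction was downward (adjusted p = 0.932). The lipase gene Lipe rose by 0.53 ± 0.12 (adjusted p = 0.00525), Fabp4, a fatty-acid binding protein, had 2 to 15 counts per vehicle and 36 to 49 per TNF-alpha library (adjusted p = 0.007), and Lpl fell by 2.00 ± 0.19 (adjusted p = 1.01e-04). Of 11 bone and cartilage markers, 3 rose, 3 fell and 5 were not past the test, and 4 rose and 4 fell when adjusted over the list alone. Their median was 0.48, in a range of -0.42 to 0.91 over the alternatives, their mean -0.33 and camera's direction upward (adjusted p = 0.862). Spp1, encoding the secreted protein osteopontin, rose from 2215 ± 151 to 5304 ± 806 CPM (1.26 ± 0.12, adjusted p = 3.92e-05) and the cartilage factor gene Sox9 by 1.10 ± 0.14 (adjusted p = 3.96e-04). Dmp1, a bone matrix protein, went from 3.04 ± 0.23 to 0.0507 ± 0.0682 CPM, with 0 to 11 counts per TNF-alpha library (adjusted p = 1.43e-04).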

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

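The alternatives that drop the decimals or keep only genes with whole counts were chosen after seeing the data; the others were fixed in advance. Among all settings that test the full set of genes at an adjusted p of 0.05, between 7414 and 8913 genes changed, and 0 genes changed in both the main and another setting had opposite directions. Of the 118 named genes tested, 108 kept their direction and their side of the threshold in each alternative that tested them. All settings draw on the same libraries, and many named genes were chosen for a large fold or a small p in the main fit. Both results were therefore likely from the start. The number of genes changed without 1 library ranged from 7414 to 8476, and of lists called by camera from 19 to 21. Upper-quartile scaling put 45.8% of the calls among rises, where the main setting put 49.8% there, and moved the median of all genes to -0.03.

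Keeping only genes with whole counts left 7402 genes to test, of which 4124 changed (1983 up and 2141 down) and 1574 changed at least 2-fold (676 up and 898 down); the lower counts follow from the smaller number of genes tested. Camera with an estimated correlation called 0 of the 28 lists, against 20 in the main setting, 2 at an unadjusted p under 0.05 and 24 with fry. Its estimated correlations reached 0.738, in the cell cycle list.

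Some differences turned round, and the cause was not tested. The Tnf log2 fold change was 0.0224 with limma-voom, 0.0276 after thinning, and between -0.206 and 0.176 without 1 library. Acta1 lay between -0.121 and 0.0245 without 1 library. The median of the autophagy list lay between -0.0105 and 0.174 without 1 library. The adipocyte list had -0.0047 with upper-quartile scaling, -0.0695 with the stricter filter and between -0.0304 and 0.0981 without 1 library, and the bone and cartilage list went from 0.48 to -0.42 with the stricter filter. Without 1 library, the difference in the Myh3 share lay between -0.0824 and 3.98 percentage points and in the Myh8 share between -1.66 and 0.492. As shares of all counts, which follow the fall of the whole family, the differences were -0.200 for Myh3, -0.016 for Myh4 and -0.0156 for Myh7.

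Libraries with the same replicate number did not deviate together (correlations of deviations 0.04, -0.051 and -0.117), and the labels do not say whether the numbers pair constructs. With the replicate block 8487 genes changed in place of 8769 and 19 lists were called in place of 20, and the Tnf log2 fold change was 0.0104. In the edgeR test with the block, Trim63 and Tnfaip3 passed (adjusted p = 0.00292 and 0.0372). Irf1 and Stc2 no longer did (adjusted p = 0.0643 and 0.0973), nor did the adhesion and protease list by camera (adjusted p = 0.0641). The planned runs without mitochondrially encoded genes were not done, since the table has none, and the planned list tests under DESeq2 or limma-voom were not run because camera takes its own log2 CPM. Depth limits the genes at the floor, such as Dmp1, Inmt and the Sprr2 genes, whose folds rest on a few counts in a group.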

Other observations

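The list of hypoxia-inducible factor targets was added after the rises of glycolysis genes were seen, and the tests of myotube share and of leukocyte RNA were also chosen only after the result was seen.

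Targets of hypoxia-inducible factor, the transcription factor that low oxygen stabilises, rose as a group. In a list of 32 tested genes, none in the other lists, 29 rose, 1 fell and 2 were not past the edgeR test, where 27.6% of all tested genes rose, and 29 rose and 1 fell when adjusted over the list alone. The median log2 fold change was 1.54 (camera p = 2.93e-11, and p = 0.12 with an estimated correlation). Ankrd37 rose 9.51-fold (3.25 ± 0.10, adjusted p = 1.13e-07). The angiogenic growth factor gene Vegfa rose from 295 ± 49.5 to 1498 ± 143 CPM (2.34 ± 0.13, adjusted p = 3.12e-06; SD, n = 3). Stc2, a stanniocalcin gene, fell by 0.49 ± 0.18 (adjusted p = 0.0442), and its adjusted p was 0.156 and 0.0876 without vehicle replicates 1 and 3 and 0.116, 0.0565 and 0.0652 without TNF-alpha replicates 1, 2 and 3 and 0.0501 with limma-voom, in a range of 0.0172 to 0.156.

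For the 16 glycolysis and glycogen genes that rose, a hypoxia-inducible factor response is a candidate explanation: 29 of the 32 other targets rose, but the estimated-correlation test that was set as the other condition gave p = 0.12, and 0 of the fixed lists passed that test after adjustment. It stays open, as do regulators that share these targets, and oxygen levels or nitric oxide were not analysed here. A trend with GC content or transcript length as the whole cause is argued against: over all tested genes it was weak, moving single genes by -0.58 to 0.19, and removing it left the list's median at 0.71. The median nearest 0 under the other scalings was 0.674, but these moved the median of all tested genes by at most 0.0343, so scaling was not put to a test and stays open.

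The fall of the adult sarcomere genes may reflect fewer or thinner myotubes. A lower share of myotube RNA as the whole cause would lower members made only in myotubes by about the same factor. In 23 of the 42 members the 95% interval lay more than 0.25 from the list's median of -0.97, 13 above it and 10 below, with Acta1 at -0.04. Which members other cells of the constructs also express was not measured, so this spread cannot decide the question. Of the satellite-cell markers 11 of 18 fell, and of the fibroblast and smooth-muscle markers 10 of 16, although Sdc4, Id2, Cd34 and Pdgfra rose. Both lists had an adjusted p = 0.415 by camera with an estimated correlation. Of the cell cycle genes 26 of 30 fell and 2 rose (median -1.94, adjusted p = 0.489 by the same test). Of the myogenic and fusion genes 16 of 21 fell, whereas 3 rose, among them Myog (0.39 ± 0.08, edgeR adjusted p = 0.00281). A lower share of myotubes would raise the markers or the cell cycle genes only if other cells carried them. Those cells must also not have been lost, nor have lowered these transcripts themselves. None of this was measured, nor which cells carry Myog, so these values do not decide the question. Removing the trend with GC content and length left the median at -0.9792, which argues against that trend as the whole cause, while the scalings, with a median of -0.9654 nearest 0, moved all genes too little to test scaling, which stays open. A lower share of myotubes, alone or together with regulation of single genes, stays open, and a direct effect of TNF-alpha on the sarcomere genes is an untested hypothesis.

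The rise of macrophage and leukocyte markers could come from leukocytes or their RNA in the TNF-alpha constructs, although C2C12 is a cell line. In the TNF-alpha libraries the median of 7 genes abundant in leukocytes (Ptprc, Tyrobp, Cd52, Coro1a, C1qa, C1qb and C1qc) was 0 of the level of the markers that rose. All of them but Coro1a had been filtered out for low counts before they were chosen. That choice settled the median, which therefore decides nothing. Tyrobp and the C1q genes had 0 counts in all 6 libraries. Ptprc had 0 counts in the TNF-alpha libraries, which allows up to 3 counts per library. Coro1a had 65 to 100 counts in the TNF-alpha libraries and 48 to 92 in the vehicle libraries. The 0 counts argue only against leukocytes that carry Ptprc, Tyrobp and the C1q genes, and leukocyte RNA without these transcripts stays open. The bound set in advance against index hopping or low depth, over 100 counts for each marker that rose in each TNF-alpha library, was not met, since Lyz2 and Fcer1g had 15 to 42 counts there, so these cannot be told apart from a rise of the list. Cd68, Itgb2 and Csf1r had 110 to 1896 counts, and their expression by the muscle cells is a hypothesis left open.

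With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. Every split but the real one holds both treatments on each side, so the treatment difference widens the spread within a side. Low counts of changed genes in those splits follow from this and do not show what chance gives. In the real split, 1 of the 10, 8769 genes changed and 2832 changed at least 2-fold, and the highest of the other splits gave 0 and 0. For gene lists called by camera with the preset correlation, the real split gave 20 and the highest of the others 15.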
